A study of Mus musculus with 8 samples.

How the data were processed

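Each of the 8 arrays measured total RNA of adherent cells from the subcutaneous fat of mice in 1 of 4 groups, with 1 colour (Cy3) on an Agilent 8x60K mouse array. Per the file headers, all arrays lay on 1 slide, read in 1 scan with Agilent Feature Extraction 11.0.1.1. The deposited processed intensity of a spot is its background-subtracted and spatially detrended brightness within its own array, per the file headers, with no normalization between arrays. The deposited median and local background intensity of a spot are unprocessed brightness, per the file headers. The authors also deposited a value table of log2 values for 38475 probes, 38346 of which match probes of the array files. Each of its columns is log2 of the processed intensity plus 1 constant per array, between −9.99 and −9.79, with slope 1; its genes are not centred. The rule behind the constant and the choice of probes is not stated. Every probe in the table is well above background on at least 1 array.

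Of 62976 spots per array, 59305 were not controls and covered 56605 probes. The 192 probes with an outlier flag on any array were left out, which left 56413. Spots of 1 probe were averaged on the log2 scale, and each array's 75th percentile was subtracted from its log2 processed intensity. A probe was kept when it was well above background, by the flag in the deposited files, on both arrays of at least 1 group, which left 37650 probes. Each gene was represented by its kept probe with the highest mean over the 8 arrays, which gave 29585 genes or unnamed features, 16732 of them with a gene symbol. The files give transcript accessions, not gene symbols. These were matched to a table of reference gene names for the assembly GRCm38.p6, which gave 1 symbol for 32907 probes (58.3%) and none for 23506. The headers name build mm9, so no coordinates are printed.

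limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 8 arrays, with 4 residual degrees of freedom and 1.87 prior degrees of freedom from the empirical Bayes step. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison over all genes tested and a threshold of 0.05 on the adjusted p. The comparisons were high-fat diet against chow at 12 and at 24 weeks, 24 against 12 weeks on each diet, the interaction, and both effects averaged. Changes are on the log2 scale. A call counts as at least 2-fold when it passes the threshold with a log2 change of 1 or more in size. Python 3.11.15 with pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the figures.

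Gene lists were tested with limma's camera at its preset correlation between genes of 0.01, two-sided, adjusted over 28 lists within a comparison, and again with the correlation estimated from the data. Each list also has its median log2 change and its members past the threshold, over all genes and adjusted over the list alone. The lists covered mesenchymal stromal markers, adipogenic regulators, mature adipocyte, osteogenic, chondrogenic, senescence and p53 target, secretory and inflammatory, cell cycle, extracellular matrix, myofibroblast and TGF-beta response, interferon response, antigen presentation, antioxidant and NRF2 target, mitochondrial respiration, endoplasmic reticulum stress, hypoxia and glycolysis, growth factor, positional, and ageing and nutrient-sensing genes. Marker lists covered macrophages, lymphocytes, endothelium, mesothelium, pericytes and smooth muscle, skeletal muscle, epithelium, Schwann cells and erythroid cells. Genes were eligible to be named by a rule: the 12 highest and 12 lowest log2 changes among called genes with a symbol, up to 4 called members of each list by smallest p, and Cdkn1a, Cdkn2a, Il6, Pparg and Mki67 in every comparison. Any other gene named is said to be chosen after its values were seen. The comparisons, lists, naming rule and alternatives were chosen before the data were examined.

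Alternatives were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization of the processed intensity, the value table of the authors, no filter on dim probes, a filter for probes well above background on all arrays, every kept probe, an intensity trend in the variance, only the groups compared, replicate number as a block, and leaving out each array in turn. Normexp was planned on the mean signal of a spot; the files hold no such column, so the deposited median intensity was used in its place. Replicate numbers were checked as pairs and do not pair the samples. The test was tested on simulated data for the 12-week diet comparison, with 29585 genes and 50 genes changed at each size. It recovered 34% of changes of 0.5, 74% of 1, 88% of 2 and 92% of 3 on the log2 scale, with 10 false calls among 29360 unchanged genes. In the same simulated data a list of 25 genes shifted by 0.5 gave a camera adjusted p of 9.87e-41 and an unshifted list 0.338. The simulated genes varied independently of each other, so these values do not show how the tests behave when genes are correlated. Far fewer genes were changed there than limma called in the data, so the recovery need not carry over.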

Results

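The mice were C57BL/6 males, 6 weeks old at the start, kept on chow or on a diet with 60% fat for 12 or 24 weeks. Cells that adhered to culture plates after collagenase digestion of abdominal subcutaneous fat were passaged and used as adipose-derived mesenchymal stromal cells, per the labels. Total RNA was hybridised to 8 one-colour mouse arrays, 2 per group, in 4 groups: chow for 12 weeks (C12), high-fat diet for 12 weeks (HF12), chow for 24 weeks (C24) and high-fat diet for 24 weeks (HF24). The labels do not say that the 2 arrays of a group come from separate animals or cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision. The 12-week arrays fill slide row 1 and the 24-week arrays row 2. Slide row and feeding time therefore cannot be told apart in any comparison of 24 with 12 weeks. The chow arrays fill slide columns 1 and 2 and the high-fat arrays columns 3 and 4. In the same way, slide column and diet cannot be told apart in any comparison of the diets.

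Probes well above background made up 65.0% to 67.2% of the probes on the 12-week arrays and 57.6% to 62.4% on the 24-week arrays. No spot was saturated, and the median intensity ran from 90.1 on both HF24 arrays to 111 on HF12 replicate 1. Across genes, which are not independent replicates, the 2 arrays of a group correlated at r = 0.995 to 0.998 and arrays of different groups at r = 0.955 to 0.985. The first 3 principal components held 56.1%, 19.5% and 15.1% of the variance. Each gene below is followed by its log2 change ± standard error (2 arrays per group), with an adjusted p under 0.05 from limma unless a p is printed. Where a gene was not well above background in the dimmer group, at least N-fold gives the mean of the brighter group over a bound, which takes on each dimmer array the larger of the gene's own value and the lowest intensity well above background.

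The comparison of high-fat diet with chow at 12 weeks asks which transcripts differ with diet after the shorter feeding. Macrophage genes were higher on the high-fat diet. In the macrophage list 17 of 18 genes were higher and 0 lower (18 and 0 adjusted over the list alone). Its median of 3.43 passed at adjusted p = 2.69e-20, and at adjusted p = 0.0137 with an estimated correlation. Examples are the Fc receptor gene Fcgr1 (4.47 ± 0.06), the complement gene C1qb (4.28 ± 0.06) and the mannose receptor gene Mrc1 (3.49 ± 0.06). Other myeloid genes were among the 12 largest increases, such as the fractalkine receptor gene Cx3cr1 (at least 64.2-fold higher), Aif1 (4.81 ± 0.06), Fcrls (4.72 ± 0.14) and the oxidase subunit gene Ncf1 (4.69 ± 0.09). Moving with them were the class II genes Cd74 (3.15 ± 0.13) and H2-Ab1 (2.19 ± 0.07), the cytokine gene Tnf (3.03 ± 0.08) and the osteopontin gene Spp1 (2.77 ± 0.05). Genes of mature adipocytes were lower. Among 22 mature adipocyte genes 1 was higher and 19 lower (2 and 20 adjusted over the list alone). Its median of −2.41, or −2.29 with undetected members at their bound, passed at adjusted p = 7.10e-13. With an estimated correlation the list passed at adjusted p = 0.0234. Examples are the lipid droplet genes Cidec (−3.79 ± 0.06) and Plin4 (−2.44 ± 0.05) and the adipokine genes Adipoq (−3.33 ± 0.07) and Retn (−4.30 ± 0.10). The 1 exception, named after its values were seen, was the fatty acid transporter gene Cd36 (1.43 ± 0.08).

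The gene encoding the adipogenic regulator PPARγ was lower too, Pparg (−1.38 ± 0.05), as was Klf15 (−1.51 ± 0.09). Of 21 adipogenic regulator genes, 2 were higher and 16 lower (2 and 16 adjusted over the list alone). Its median of −0.48 passed at adjusted p = 1.10e-04, and missed at adjusted p = 0.0884 with an estimated correlation. Major urinary protein genes, whose near-identical copies one probe may not tell apart, held 10 of the 12 largest decreases, among them Mup1 (−5.30 ± 0.08), Mup18 (−5.27 ± 0.10) and Mup21 (−5.25 ± 0.08). The cytochrome gene Cyp2e1 (−5.02 ± 0.08) was another. Interferon response genes leaned lower, with Cxcl9 (−2.18 ± 0.05), Ifi44 (−1.51 ± 0.07) and Usp18 (−1.20 ± 0.06). In the interferon response list 2 of 30 genes were higher and 22 lower (2 and 22 adjusted over the list alone). Its median of −0.64 passed at adjusted p = 9.00e-07, and missed at adjusted p = 0.107 with an estimated correlation. The 2 exceptions, named after their values were seen, were Oas3 (1.64 ± 0.16) and Rsad2 (0.46 ± 0.13). The call for Rsad2 was lost without any 1 array other than C12 replicate 2, with adjusted p from 0.0576 to 0.174. Respiration genes leaned lower, with Acadm (−0.78 ± 0.06) and Ppargc1a (−2.26 ± 0.21). Among 24 mitochondrial respiration genes 1 was higher and 18 lower (1 and 19 adjusted over the list alone). Its median of −0.44 passed at adjusted p = 3.83e-06, and missed at adjusted p = 0.107 with an estimated correlation. The 1 exception, named after its values were seen, was Cpt1a (0.63 ± 0.08). Among stromal markers Nt5e (−3.31 ± 0.09) and Dpp4 (−2.06 ± 0.05) were lower and Alcam (1.88 ± 0.09) was higher.

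Cell cycle genes leaned higher by small amounts. Of 32 cell cycle genes, 12 were higher and 2 lower (12 and 2 adjusted over the list alone). Its median of 0.15 passed at adjusted p = 0.0111, and missed at adjusted p = 0.107 with an estimated correlation. Examples are Ccnd1 (1.33 ± 0.06), Pcna (0.78 ± 0.06) and Mki67 (0.37 ± 0.06). Contractile and TGF-beta response genes also leaned higher, with Tgfbi (2.16 ± 0.06) and Cnn1 (0.76 ± 0.05). In the myofibroblast and TGF-beta response list 12 of 20 genes were higher and 3 lower (12 and 3 adjusted over the list alone). Its median of 0.30 passed at adjusted p = 0.00252, and missed at adjusted p = 0.107 with an estimated correlation. The cyclin-dependent kinase inhibitor gene Cdkn1a (0.36 ± 0.09) was higher, a call lost without C12 replicate 1 (adjusted p = 0.122), HF12 replicate 1 (0.124) or HF12 replicate 2 (0.0988). The call for Cdkn2a (0.29 ± 0.10, adjusted p = 0.0702) did not pass, and Il6 (−0.49 ± 0.09) was lower, a call lost without HF12 replicate 1 (adjusted p = 0.0654). The senescence and p53 target (median 0.12, adjusted p = 0.191) list did not pass.

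limma called 9263 of 29585 genes between the diets at 12 weeks, 4065 higher and 5198 lower on the high-fat diet; 1189 were higher and 945 lower by at least 2-fold, or 761 and 529 with normexp and 858 and 548 among genes well above background on all arrays. The count was 6077 without C12 replicate 1, 5440 without HF12 replicate 1 and 5825 without HF12 replicate 2, and the higher and lower calls were 2877 and 3200, 2557 and 2883, and 2577 and 3248 in that order. With an estimated correlation between genes, only the macrophage and mature adipocyte calls held in this comparison.

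Other lists passed with the preset correlation alone. Mesenchymal stromal genes had 2 of 17 higher and 8 lower (2 and 9 adjusted over the list alone), a median of −0.19 and adjusted p = 0.194 with an estimated correlation. Hypoxia and glycolysis genes had 10 of 19 higher and 4 lower (10 and 4 adjusted over the list alone), a median of 0.21 and adjusted p = 0.173 with an estimated correlation. Positional genes had 2 of 21 higher and 11 lower (2 and 13 adjusted over the list alone), a median of −0.29 and adjusted p = 0.316 with an estimated correlation. Endothelial genes had 1 of 13 higher and 8 lower (1 and 9 adjusted over the list alone), a median of −0.35 and adjusted p = 0.173 with an estimated correlation. Mesothelial genes had 2 of 6 higher and 0 lower (3 and 0 adjusted over the list alone), a median of 0.44, or 0.38 with undetected members at their bound, and adjusted p = 0.247 with an estimated correlation. Endothelial genes lost their call without C12 replicate 2 (adjusted p = 0.0651) and without HF12 replicate 2 (adjusted p = 0.0507). Hypoxia and glycolysis genes lost their call without C12 replicate 2 (adjusted p = 0.0651) and without HF12 replicate 1 (adjusted p = 0.0533). Mesenchymal stromal genes lost their call without HF12 replicate 1 (adjusted p = 0.0533). Mesothelial genes lost their call without C12 replicate 1 (adjusted p = 0.0543), without C12 replicate 2 (adjusted p = 0.0695) and without HF12 replicate 1 (adjusted p = 0.0897). Positional genes lost their call without C12 replicate 1 (adjusted p = 0.0501) and without HF12 replicate 1 (adjusted p = 0.0616). Schwann and glial genes passed without HF12 replicate 2 (adjusted p = 0.0454), without HF24 replicate 1 (adjusted p = 0.0411) and without HF24 replicate 2 (adjusted p = 0.0411). Growth and angiogenic factor genes passed without HF12 replicate 1 (adjusted p = 0.0482). The osteogenic (median 0.11, adjusted p = 0.427), chondrogenic (median −0.27, adjusted p = 0.469) and antioxidant and NRF2 target (median 0.03, adjusted p = 0.953) lists did not pass. The endoplasmic reticulum stress (median 0.08, adjusted p = 0.0947), growth and angiogenic factor (median −0.25, adjusted p = 0.0535) and ageing and nutrient-sensing (median −0.17, adjusted p = 0.200) lists missed the threshold. The lymphocyte (median 0.02, adjusted p = 0.731), skeletal muscle and myoblast (median −0.22, adjusted p = 0.127) and epithelial and keratinocyte (median 0.19, adjusted p = 0.243) lists did not pass. The Schwann and glial (median 0.28, adjusted p = 0.0530) list missed the threshold. Median, mean and test differed in sign for the next lists. The secretory and inflammatory (median −0.15, or −0.01 at the bound, mean 0.06, test downward, adjusted p = 0.712), extracellular matrix (median 0.06, mean −0.06, test upward, adjusted p = 0.731) and antigen presentation (median −0.09, mean 0.54, test upward, adjusted p = 0.321) lists did not pass.

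The same diet comparison after 24 weeks covers the longer feeding. Proliferation genes were higher on the high-fat diet. Among 32 cell cycle genes 30 were higher and 0 lower (30 and 1 adjusted over the list alone). Its median of 0.81, or 0.80 with undetected members at their bound, passed at adjusted p = 2.19e-17. Examples are the topoisomerase gene Top2a (0.97 ± 0.05), Nusap1 (0.98 ± 0.06), Bub1 (0.96 ± 0.06) and the proliferation marker gene Mki67 (0.91 ± 0.06). Antigen presentation genes were higher, with the class II gene H2-Eb1 (1.89 ± 0.06), Cd74 (2.67 ± 0.13) and the immunoproteasome gene Psmb9 (1.39 ± 0.06). Of 18 antigen presentation genes, 17 were higher and 0 lower (17 and 0 adjusted over the list alone). Its median of 0.88 passed at adjusted p = 1.42e-11. Macrophage genes were again higher, with Fcgr1 (1.89 ± 0.06), C1qb (1.74 ± 0.06) and Cd14 (1.40 ± 0.06). In the macrophage list 15 of 18 genes were higher and 1 lower (15 and 2 adjusted over the list alone). Its median of 0.95 passed at adjusted p = 1.08e-09. Against the list, and named after its values were seen, went Itgam (−0.36 ± 0.07). The call for Itgam was lost without HF24 replicate 2 (adjusted p = 0.0540). Large increases included Cx3cr1 (at least 25.5-fold higher), the calprotectin gene S100a9 (at least 38.2-fold higher), the arginase gene Arg1 (at least 7.72-fold higher), the interferon gamma gene Ifng (at least 2.94-fold higher) and Ubd (3.02 ± 0.09). Endothelial genes were higher, with Vwf (1.34 ± 0.07) and Cldn5 (0.66 ± 0.08). Among 13 endothelial genes 9 were higher and 0 lower (10 and 0 adjusted over the list alone). Its median of 0.36 passed at adjusted p = 2.33e-04.

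Genes of other lineages were lower on the high-fat diet at 24 weeks. Skeletal muscle genes such as Tnnc2 (−2.44 ± 0.07), Chrna1 (−1.87 ± 0.06) and Myog (−1.79 ± 0.06) were lower. Of 11 skeletal muscle and myoblast genes, 0 were higher and 10 lower (0 and 10 adjusted over the list alone). Its median of −1.87, or −1.79 with undetected members at their bound, passed at adjusted p = 6.09e-08. Keratinocyte genes such as Krt5 (−3.54 ± 0.13), Krt14 (−3.28 ± 0.20) and Perp (−2.81 ± 0.06) were lower. In the epithelial and keratinocyte list 0 of 8 genes were higher and 7 lower (0 and 8 adjusted over the list alone). Its median of −2.11, or −1.43 with undetected members at their bound, passed at adjusted p = 7.06e-06. Schwann cell genes such as Sox10 (−1.39 ± 0.09) were lower. Among 7 Schwann and glial genes 0 were higher and 7 lower (0 and 7 adjusted over the list alone). Its median of −1.32, or −1.24 with undetected members at their bound, passed at adjusted p = 1.34e-05. Genes of secreted growth factors were lower, with Vegfd (−2.14 ± 0.06), Igf2 (−1.98 ± 0.08) and Ptn (−2.41 ± 0.11). Of 22 growth and angiogenic factor genes, 2 were higher and 16 lower (3 and 16 adjusted over the list alone). Its median of −0.48 passed at adjusted p = 8.87e-05. The 2 exceptions, named after their values were seen, were Pgf (0.42 ± 0.06) and Mdk (0.26 ± 0.06). The call for Mdk was lost without C24 replicate 1 (adjusted p = 0.0994) or HF24 replicate 1 (adjusted p = 0.119). The adipokine genes Cfd (at least 14.1-fold lower) and Adipoq (at least 5.35-fold lower) and the lipid gene Plin1 (−1.60 ± 0.09) were among the decreases, although the list as a whole did not pass: mature adipocyte (median −0.08, or −0.05 at the bound, adjusted p = 0.143). Its members had 3 of 22 higher and 9 lower (4 and 9 adjusted over the list alone). It passed without HF24 replicate 1 (adjusted p = 0.0396).

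Interferon genes went both ways, with Cxcl9 (2.81 ± 0.05) higher and Oas2 (−1.50 ± 0.06) and Isg15 (−1.28 ± 0.06) lower; the list did not pass: interferon response (median −0.29, adjusted p = 0.0729). The cell cycle inhibitor genes Cdkn1c (−1.51 ± 0.06), Cdkn2b (−0.63 ± 0.06) and Cdkn2a (−0.86 ± 0.10) were lower, Cdkn1a (−0.16 ± 0.09, adjusted p = 0.228) did not pass, and neither did the senescence list: senescence and p53 target (median −0.15, adjusted p = 0.0602). Il6 (−0.79 ± 0.09) was lower, and Pparg (0.20 ± 0.05) was higher, a call lost without any 1 of the HF12, C24 or HF24 arrays, with adjusted p from 0.0567 to 0.129.

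At 24 weeks limma called 9805 genes, 3821 higher and 5984 lower; 402 were higher and 1830 lower by at least 2-fold, or 534 and 1347 under quantile normalization, 159 and 467 with normexp before it and 229 and 1068 among genes well above background on all arrays. All higher and lower calls were 4540 and 5099 under quantile normalization. The higher calls fell to 2347 without C24 replicate 1, 2248 without HF24 replicate 1 and 2472 without HF24 replicate 2. The calls that held with an estimated correlation were cell cycle, antigen presentation, macrophage, growth factor, endothelial, skeletal muscle, epithelial and Schwann genes. Their camera adjusted p then ran from 0.0149 (cell cycle) to 0.0471 (endothelial).

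Other lists passed with the preset correlation alone. Chondrogenic genes had 0 of 13 higher and 7 lower (1 and 10 adjusted over the list alone), a median of −0.30, or −0.28 with undetected members at their bound, and adjusted p = 0.137 with an estimated correlation. Hypoxia and glycolysis genes had 6 of 19 higher and 3 lower (10 and 3 adjusted over the list alone), a median of 0.19 and adjusted p = 0.123 with an estimated correlation. Lymphocyte genes had 4 of 9 higher and 0 lower (4 and 0 adjusted over the list alone), a median of 0.15, or 0.10 with undetected members at their bound, and adjusted p = 0.137 with an estimated correlation. Mesothelial genes had 0 of 6 higher and 5 lower (0 and 5 adjusted over the list alone), a median of −1.25 and adjusted p = 0.137 with an estimated correlation. Pericyte and smooth muscle genes had 6 of 11 higher and 1 lower (6 and 1 adjusted over the list alone), a median of 0.26 and adjusted p = 0.137 with an estimated correlation. Lymphocyte genes lost their call without C24 replicate 2 (adjusted p = 0.0864) and without HF24 replicate 1 (adjusted p = 0.0662). Pericyte and smooth muscle genes lost their call without HF24 replicate 1 (adjusted p = 0.0843). Median, mean and test differed in sign for the next lists. The osteogenic (median −0.02, or 0.00 at the bound, mean −0.03, test upward, adjusted p = 0.812), myofibroblast and TGF-beta response (median −0.04, mean 0.06, test upward, adjusted p = 0.558) and ageing and nutrient-sensing (median −0.02, mean 0.01, test upward, adjusted p = 0.763) lists did not pass.

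The comparison of 24 with 12 weeks on chow asks which transcripts differ with age and time alone, here together with slide row. Adipocyte genes were lower at 24 weeks, with the adiponectin gene Adipoq (−9.17 ± 0.07), Cidec (−6.49 ± 0.06) and Plin4 (−4.35 ± 0.05). In the mature adipocyte list 0 of 22 genes were higher and 20 lower (0 and 20 adjusted over the list alone). Its median of −3.08, or −2.80 with undetected members at their bound, passed at adjusted p = 6.96e-16. Other large decreases were the urinary protein gene Mup1 (at least 733-fold lower), the beta-3 adrenergic receptor gene Adrb3 (−10.07 ± 0.15) and the carbonic anhydrase gene Car3 (−8.98 ± 0.19). The adipogenic regulator genes Pparg (−1.91 ± 0.05), Dlk1 (−2.89 ± 0.09) and Klf15 (−2.42 ± 0.09) were lower. The list of such regulators does not tell genes that promote adipogenesis from genes that restrain it. Among 21 adipogenic regulator genes 5 were higher and 9 lower (6 and 11 adjusted over the list alone). Its median of −0.23 passed at adjusted p = 0.0384, and missed at adjusted p = 0.136 with an estimated correlation. Adipogenic regulator genes lost their call without C12 replicate 1 (adjusted p = 0.0504) and without C24 replicate 2 (adjusted p = 0.0513). Secretory and inflammatory genes were higher, with Tnf (3.80 ± 0.08), Ptgs2 (2.64 ± 0.09), Cxcl1 (2.28 ± 0.09) and Il6 (1.98 ± 0.09). Of 28 secretory and inflammatory genes, 23 were higher and 1 lower (23 and 1 adjusted over the list alone). Its median of 1.21, or 1.18 with undetected members at their bound, passed at adjusted p = 1.43e-09. The 1 exception, named after its values were seen, was Mmp3 (−0.62 ± 0.06). Macrophage genes were higher with them, such as Fcgr1 (2.24 ± 0.06) and C1qa (3.17 ± 0.09), and so were Acod1 (6.68 ± 0.09) and Ccl12 (5.46 ± 0.05). In the macrophage list 16 of 18 genes were higher and 0 lower (18 and 0 adjusted over the list alone). Its median of 1.91 passed at adjusted p = 2.48e-11.

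Posterior Hox genes were among the largest increases on chow, with Hoxc10 (at least 51.9-fold higher), Hoxc11 (at least 24.5-fold higher) and Hoxa10 (2.39 ± 0.09); the positional list also held lower members such as Hoxd8 (−0.96 ± 0.06) and did not pass: positional (median −0.30, mean 0.15, test downward, adjusted p = 0.149). Keratinocyte genes were higher, with Krt14 (5.57 ± 0.20), Krt5 (5.10 ± 0.13) and Perp (2.60 ± 0.06). Among 8 epithelial and keratinocyte genes 6 were higher and 1 lower (6 and 1 adjusted over the list alone). Its median of 2.19, or 2.01 with undetected members at their bound, passed at adjusted p = 3.22e-04. Against the list, and named after its values were seen, went Trp63 (−0.24 ± 0.07). The call for Trp63 was lost without any 1 array other than HF24 replicate 1 and HF24 replicate 2, with adjusted p from 0.0517 to 0.132. Endothelial genes were higher, with Cldn5 (1.34 ± 0.08) and Pecam1 (0.96 ± 0.06). Of 13 endothelial genes, 12 were higher and 1 lower (12 and 1 adjusted over the list alone). Its median of 0.96 passed at adjusted p = 3.42e-05. The 1 exception, named after its values were seen, was Tek (−0.70 ± 0.10). Skeletal muscle genes were lower, with Tnnc2 (−1.70 ± 0.07) and Chrna1 (−1.25 ± 0.06). In the skeletal muscle and myoblast list 0 of 11 genes were higher and 11 lower (0 and 11 adjusted over the list alone). Its median of −1.21, or −1.10 with undetected members at their bound, passed at adjusted p = 6.26e-07.

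Stress response genes were higher at 24 weeks on chow, with the glutathione enzyme gene Chac1 (1.27 ± 0.06) and the serine synthesis gene Psat1 (0.93 ± 0.06). Among 20 endoplasmic reticulum stress genes 15 were higher and 0 lower (15 and 0 adjusted over the list alone). Its median of 0.55 passed at adjusted p = 3.46e-06. Hypoxia genes were higher, with Car9 (1.82 ± 0.09) and Hif1a (0.82 ± 0.05). Of 19 hypoxia and glycolysis genes, 14 were higher and 1 lower (15 and 1 adjusted over the list alone). Its median of 0.72 passed at adjusted p = 2.29e-05. Against the list, and named after its values were seen, went Bnip3 (−0.54 ± 0.08). TGF-beta response genes were higher, with Ccn1 (1.31 ± 0.07) and Ccn2 (0.82 ± 0.06), and the 2 exceptions were Id1 (−0.93 ± 0.06) and, named after its values were seen, Id3 (−0.30 ± 0.06). The call for Id3 was lost without C24 replicate 1 (adjusted p = 0.0539). In the myofibroblast and TGF-beta response list 16 of 20 genes were higher and 2 lower (16 and 2 adjusted over the list alone). Its median of 0.64 passed at adjusted p = 4.49e-05. Respiration genes were lower, with Ppargc1a (−4.70 ± 0.21) and Acadm (−1.33 ± 0.06). Among 24 mitochondrial respiration genes 0 were higher and 21 lower (0 and 21 adjusted over the list alone). Its median of −0.46 passed at adjusted p = 6.40e-08. Cdkn1a (−0.57 ± 0.09) and Mki67 (−0.31 ± 0.06) were lower; Cdkn2a (−0.05 ± 0.10, adjusted p = 0.710) did not pass, and its probes differed in direction. The senescence list did not pass: senescence and p53 target (median −0.11, adjusted p = 0.227), although Igfbp3 (1.80 ± 0.05) and Btg2 (1.26 ± 0.09) were higher.

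limma called 13759 genes between the times on chow, 7263 higher and 6496 lower at 24 weeks; 1366 were higher and 1852 lower by at least 2-fold, or 693 and 900 with normexp and 985 and 1000 among genes well above background on all arrays. Without the filter on dim probes, 67.7% of the calls were higher in place of 52.8%. The lower calls were the more numerous under quantile normalization (6793 higher and 6944 lower) and with normexp before it (6849 and 7318). With an estimated correlation the adipocyte, secretory, macrophage, respiration, endoplasmic reticulum stress, hypoxia, myofibroblast, endothelial, skeletal muscle and epithelial calls held. Their camera adjusted p then ran from 0.0222 (adipocyte and macrophage) to 0.0456 (respiration and epithelial).

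Other lists passed with the preset correlation alone. Cell cycle genes had 5 of 32 higher and 15 lower (6 and 16 adjusted over the list alone), a median of −0.19 and adjusted p = 0.136 with an estimated correlation. Extracellular matrix genes had 14 of 31 higher and 5 lower (15 and 5 adjusted over the list alone), a median of 0.16 and adjusted p = 0.291 with an estimated correlation. Mesothelial genes had 4 of 6 higher and 0 lower (4 and 0 adjusted over the list alone), a median of 1.53 and adjusted p = 0.186 with an estimated correlation. Pericyte and smooth muscle genes had 7 of 11 higher and 2 lower (7 and 2 adjusted over the list alone), a median of 0.39 and adjusted p = 0.154 with an estimated correlation. Schwann and glial genes had 5 of 7 higher and 1 lower (6 and 1 adjusted over the list alone), a median of 0.55 and adjusted p = 0.154 with an estimated correlation. Schwann and glial genes lost their call without C12 replicate 1 (adjusted p = 0.0504), without C12 replicate 2 (adjusted p = 0.0629), without C24 replicate 1 (adjusted p = 0.0638) and without C24 replicate 2 (adjusted p = 0.0546). Cell cycle genes lost their call without C24 replicate 1 (adjusted p = 0.0638), without C24 replicate 2 (adjusted p = 0.0507), without HF24 replicate 1 (adjusted p = 0.0508) and without HF24 replicate 2 (adjusted p = 0.0508). Extracellular matrix genes lost their call without C12 replicate 1 (adjusted p = 0.0704) and without C24 replicate 2 (adjusted p = 0.0734). Pericyte and smooth muscle genes lost their call without C12 replicate 1 (adjusted p = 0.0576) and without C24 replicate 2 (adjusted p = 0.0513). Median, mean and test differed in sign for the next lists and for the positional list. The mesenchymal stromal (median 0.10, mean −0.17, test downward, adjusted p = 0.912), antigen presentation (median −0.09, mean 0.14, test downward, adjusted p = 0.912) and antioxidant and NRF2 target (median 0.09, mean −0.11, test downward, adjusted p = 0.613) lists did not pass.

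The same comparison on the high-fat diet asks which transcripts differ with time under that diet. Adipocyte genes were lower at 24 weeks here too, with Adipoq (at least 307-fold lower), Cfd (at least 1215-fold lower) and Plin1 (−5.64 ± 0.09). Of 22 mature adipocyte genes, 2 were higher and 18 lower (3 and 18 adjusted over the list alone). Its median of −1.26 passed at adjusted p = 8.32e-08. The 2 exceptions, named after their values were seen, were Slc2a4 (0.84 ± 0.06) and Pck1, which was not well above background in either group. Skeletal muscle genes were lower, with Chrna1 (−3.04 ± 0.06), Tnnc2 (−3.53 ± 0.07) and Myog (−2.89 ± 0.06). In the skeletal muscle and myoblast list 0 of 11 genes were higher and 11 lower (0 and 11 adjusted over the list alone). Its median of −2.97, or −2.89 with undetected members at their bound, passed at adjusted p = 6.32e-09. Secretory and inflammatory genes were higher, with Ptgs2 (2.33 ± 0.09), Saa3 (1.27 ± 0.06), Cxcl1 (1.94 ± 0.09) and Il6 (1.68 ± 0.09). Among 28 secretory and inflammatory genes 24 were higher and 1 lower (24 and 1 adjusted over the list alone). Its median of 1.03 passed at adjusted p = 5.84e-11. The 1 exception, named after its values were seen, was Icam1 (−0.34 ± 0.08). The call for Icam1 was lost without HF12 replicate 1 (adjusted p = 0.0766) or HF24 replicate 1 (adjusted p = 0.0637) or HF24 replicate 2 (adjusted p = 0.0542). Replication genes were higher, with Ccne1 (0.60 ± 0.05), Mcm7 (0.71 ± 0.06) and Rrm2 (0.79 ± 0.07), while Ccnd1 (−1.09 ± 0.06) was the 1 exception. Of 32 cell cycle genes, 27 were higher and 1 lower (28 and 1 adjusted over the list alone). Its median of 0.52 passed at adjusted p = 4.35e-09. Endothelial genes were higher, with Cldn5 (2.40 ± 0.08), Erg (2.09 ± 0.08) and Cdh5 (1.71 ± 0.07). In the endothelial list 12 of 13 genes were higher and 0 lower (12 and 0 adjusted over the list alone). Its median of 1.56 passed at adjusted p = 2.44e-09.

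Hypoxia genes were higher at 24 weeks on the high-fat diet, with Vegfa (0.98 ± 0.07) and Hif1a (0.86 ± 0.05). Among 19 hypoxia and glycolysis genes 16 were higher and 2 lower (16 and 2 adjusted over the list alone). Its median of 0.59 passed at adjusted p = 3.03e-06. The 2 exceptions, named after their values were seen, were Car9 (−0.35 ± 0.09) and Adm (−0.20 ± 0.06). The call for Car9 was lost without any 1 of the HF12 or HF24 arrays, with adjusted p from 0.0633 to 0.0876. The call for Adm was lost without any 1 array other than C12 replicate 1 and C12 replicate 2, with adjusted p from 0.0528 to 0.171. Pericyte genes were higher, with Rgs5 (2.60 ± 0.08) and Kcnj8 (2.97 ± 0.09), while Des (−1.73 ± 0.07) was the 1 exception. Of 11 pericyte and smooth muscle genes, 10 were higher and 1 lower (10 and 1 adjusted over the list alone). Its median of 0.81 passed at adjusted p = 1.71e-05. Immune genes with large increases were S100a9 (at least 60.7-fold higher), Gzmb (at least 11.8-fold higher) and Acod1 (5.19 ± 0.09), and the interferon genes Cxcl9 (3.74 ± 0.05) and Gbp2 (1.87 ± 0.07) were higher. In the interferon response list 17 of 30 genes were higher and 5 lower (17 and 5 adjusted over the list alone). Its median of 0.26 passed at adjusted p = 6.79e-05, and missed at adjusted p = 0.0852 with an estimated correlation. Macrophage genes leaned lower on this diet, with Mrc1 (−1.48 ± 0.06), Cd68 (−0.69 ± 0.06) and Csf1r (−0.56 ± 0.05). Among 18 macrophage genes 2 were higher and 14 lower (2 and 14 adjusted over the list alone). Its median of −0.47 passed at adjusted p = 7.36e-04, and missed at adjusted p = 0.0536 with an estimated correlation. The 2 exceptions, named after their values were seen, were C1qa (0.76 ± 0.09) and C1qc (0.26 ± 0.07). The call for C1qc was lost without any 1 of the HF12 or HF24 arrays, with adjusted p from 0.0599 to 0.123. Posterior Hox genes were higher again, with Hoxc11 (at least 23-fold higher) and Hoxa10 (3.08 ± 0.09), and the positional list did not pass: positional (median 0.10, adjusted p = 0.256).

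Cell cycle inhibitor genes were lower at 24 weeks on the high-fat diet, with Cdkn1c (−2.46 ± 0.06), Cdkn2b (−1.67 ± 0.06), Cdkn2a (−1.20 ± 0.10) and Cdkn1a (−1.09 ± 0.09), while Igfbp3 (1.92 ± 0.05) was higher. Of 24 senescence and p53 target genes, 6 were higher and 14 lower (6 and 14 adjusted over the list alone). Its median of −0.35 passed at adjusted p = 0.0385, and missed at adjusted p = 0.111 with an estimated correlation. Senescence and p53 target genes lost their call without C24 replicate 1 (adjusted p = 0.0542), without C24 replicate 2 (adjusted p = 0.0542), without HF12 replicate 1 (adjusted p = 0.0609) and without HF24 replicate 2 (adjusted p = 0.0607). Pparg (−0.33 ± 0.05) and the growth factor gene Igf2 (−3.43 ± 0.08) were lower. Mki67 (0.23 ± 0.06) was higher, a call lost without any 1 of the HF12 or HF24 arrays, with adjusted p from 0.0818 to 0.111, and under quantile normalization with or without normexp background correction.

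limma called 13795 genes between the times on the high-fat diet, 6248 higher and 7547 lower; 704 were higher and 2157 lower by at least 2-fold, or 413 and 744 with normexp, 529 and 1098 among genes well above background on all arrays and 1211 and 2283 without the filter on dim probes. Without the filter on dim probes, 63.4% of the calls were higher in place of 45.3%. The higher calls fell to 3790 without HF12 replicate 1 and 4072 without HF24 replicate 1, and among genes well above background on all arrays 6507 were higher and 6260 lower. The adipocyte, secretory, cell cycle, hypoxia, endothelial, skeletal muscle and pericyte calls held with an estimated correlation.

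Other lists passed with the preset correlation alone. Mesenchymal stromal genes had 11 of 17 higher and 2 lower (12 and 2 adjusted over the list alone), a median of 0.31 and adjusted p = 0.0852 with an estimated correlation. Chondrogenic genes had 0 of 13 higher and 7 lower (0 and 7 adjusted over the list alone), a median of −0.29 and adjusted p = 0.111 with an estimated correlation. Extracellular matrix genes had 12 of 31 higher and 4 lower (12 and 4 adjusted over the list alone), a median of 0.12 and adjusted p = 0.230 with an estimated correlation. Myofibroblast and TGF-beta response genes had 12 of 20 higher and 4 lower (12 and 4 adjusted over the list alone), a median of 0.39 and adjusted p = 0.0839 with an estimated correlation. The extracellular matrix median was −0.01 under quantile normalization, with or without normexp. Antigen presentation genes had 14 of 18 higher and 0 lower (16 and 0 adjusted over the list alone), a median of 0.67 and adjusted p = 0.0556 with an estimated correlation. Endoplasmic reticulum stress genes had 10 of 20 higher and 1 lower (10 and 1 adjusted over the list alone), a median of 0.26 and adjusted p = 0.0518 with an estimated correlation. Lymphocyte genes had 4 of 9 higher and 0 lower (4 and 0 adjusted over the list alone), a median of 0.64 and adjusted p = 0.0795 with an estimated correlation. Schwann and glial genes had 0 of 7 higher and 6 lower (0 and 6 adjusted over the list alone), a median of −1.21, or −1.16 with undetected members at their bound, and adjusted p = 0.0607 with an estimated correlation. Median, mean and test differed in sign for the next lists. The adipogenic regulator (median 0.07, mean −0.19, test upward, adjusted p = 0.783), osteogenic (median 0.14, mean −0.19, test upward, adjusted p = 0.811) and growth and angiogenic factor (median 0.13, mean −0.23, test upward, adjusted p = 0.811) lists did not pass. The erythroid (median −0.00, mean −0.00, test upward, adjusted p = 0.745) list missed the threshold.

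The interaction asks whether the diet effect differs between 24 and 12 weeks, given as the log2 effect at 24 weeks minus that at 12 weeks. List medians for the interaction were not bounded, so undetected members enter them at their own values. The effect on macrophage genes was smaller at 24 weeks, with Mrc1 (−3.67 ± 0.08), Fcgr1 (−2.58 ± 0.08) and Cd68 (−2.36 ± 0.08). In the macrophage list 0 of 18 genes were upward and 17 downward (0 and 17 adjusted over the list alone). Its median of −2.40 passed at adjusted p = 2.20e-14. That on adipocyte genes moved upward, with Cidec (3.53 ± 0.08) and Agpat2 (2.20 ± 0.07) and, outside that list, Pparg (1.58 ± 0.07). Among 22 mature adipocyte genes 16 were upward and 3 downward (16 and 3 adjusted over the list alone). Its median of 1.82 passed at adjusted p = 1.98e-08. The 3 exceptions were Cfd, not well above background on HF24, and, named after their values were seen, Lpl (−0.48 ± 0.08) and Cd36 (−1.24 ± 0.11). Cell cycle genes moved upward, with Cenpf (1.17 ± 0.12) and Kif20a (1.18 ± 0.12), while Ccnd1 (−1.52 ± 0.09) was the 1 exception. Of 32 cell cycle genes, 27 were upward and 1 downward (29 and 1 adjusted over the list alone). Its median of 0.68 passed at adjusted p = 2.68e-11. Endothelial genes moved upward with Plvap (1.24 ± 0.13) and Cldn5 (1.06 ± 0.11). In the endothelial list 9 of 13 genes were upward and 0 downward (11 and 0 adjusted over the list alone). Its median of 0.65 passed at adjusted p = 3.12e-06. Lineage genes moved downward. Skeletal muscle genes did so with Chrna1 (−1.79 ± 0.08) and Myog (−1.79 ± 0.08). Among 11 skeletal muscle and myoblast genes 1 was upward and 9 downward (1 and 9 adjusted over the list alone). Its median of −1.79 passed at adjusted p = 6.55e-06. Epithelial genes did so with Perp (−3.28 ± 0.08) and Krt5 (−3.78 ± 0.18). Of 8 epithelial and keratinocyte genes, 0 were upward and 6 downward (0 and 7 adjusted over the list alone). Its median of −2.18 passed at adjusted p = 1.25e-05. Schwann cell genes did so with Sox10 (−1.76 ± 0.13). In the Schwann and glial list 0 of 7 genes were upward and 7 downward (0 and 7 adjusted over the list alone). Its median of −1.76 passed at adjusted p = 1.12e-05.

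The interaction was upward for Ubd (5.72 ± 0.13), Cxcl9 (4.99 ± 0.07), Nt5e (2.90 ± 0.13) and Kcnj8 (2.62 ± 0.13) and downward for Tnf (−2.33 ± 0.12), Atf3 (−2.51 ± 0.07), Cdkn1c (−2.33 ± 0.08) and Cdkn2a (−1.15 ± 0.14). Mki67 (0.53 ± 0.08) moved upward, and Il6 (−0.30 ± 0.13, adjusted p = 0.141) did not pass, although it did without C12 replicate 1 (adjusted p = 0.0422). Cdkn1a (−0.53 ± 0.13) was downward, a call lost without any 1 array other than C12 replicate 2 and C24 replicate 1, with adjusted p from 0.0641 to 0.0894. limma called 8780 genes for the interaction, 3770 upward and 5010 downward; 989 and 2117 of them by at least 2-fold. All upward and downward calls numbered 4374 and 4402 under quantile normalization and 4700 and 4443 with normexp before it, so the lean of all calls depends on the scaling. The calls of at least 2-fold leaned downward under both, with 1191 and 1737 and 584 and 891, and among genes well above background on all arrays, with 614 and 1429. The upward calls fell to 2446 without HF12 replicate 1. All lists named above for the interaction held with an estimated correlation.

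Other lists passed with the preset correlation alone. Mesenchymal stromal genes had 4 of 17 upward and 1 downward (4 and 1 adjusted over the list alone), a median of 0.19 and adjusted p = 0.160 with an estimated correlation. Adipogenic regulator genes had 9 of 21 upward and 2 downward (9 and 3 adjusted over the list alone), a median of 0.23 and adjusted p = 0.0829 with an estimated correlation. Interferon response genes had 13 of 30 upward and 7 downward (13 and 8 adjusted over the list alone), a median of 0.17 and adjusted p = 0.209 with an estimated correlation. Antigen presentation genes had 12 of 18 upward and 2 downward (12 and 2 adjusted over the list alone), a median of 0.53 and adjusted p = 0.136 with an estimated correlation. Mitochondrial respiration genes had 17 of 24 upward and 1 downward (19 and 1 adjusted over the list alone), a median of 0.47 and adjusted p = 0.0576 with an estimated correlation. Positional genes had 8 of 21 upward and 2 downward (9 and 2 adjusted over the list alone), a median of 0.28 and adjusted p = 0.210 with an estimated correlation. Mesothelial genes had 0 of 6 upward and 4 downward (0 and 5 adjusted over the list alone), a median of −1.37 and adjusted p = 0.123 with an estimated correlation. The pericyte and smooth muscle (median 0.35, adjusted p = 0.0575), endoplasmic reticulum stress (median −0.19, adjusted p = 0.0575) and ageing and nutrient-sensing (median 0.10, adjusted p = 0.0629) lists did not pass. The lymphocyte (median 0.13, adjusted p = 0.116) list missed the threshold. Ageing and nutrient-sensing genes passed without HF12 replicate 1 (adjusted p = 0.0493) and without HF24 replicate 1 (adjusted p = 0.0434). Endoplasmic reticulum stress genes passed without C12 replicate 1 (adjusted p = 0.0446) and without HF12 replicate 1 (adjusted p = 0.0493). Lymphocyte genes passed without C12 replicate 1 (adjusted p = 0.0446). Pericyte and smooth muscle genes passed without C12 replicate 1 (adjusted p = 0.0333), without C24 replicate 2 (adjusted p = 0.0430), without HF12 replicate 1 (adjusted p = 0.0479) and without HF24 replicate 2 (adjusted p = 0.0307).

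Averaged over both times, 12331 genes differed between the diets, 4944 higher and 7387 lower on the high-fat diet. With an estimated correlation the macrophage, adipocyte, cell cycle and skeletal muscle calls held, with examples Aif1 (3.79 ± 0.04), Fcgr1 (3.18 ± 0.04), Cidec (−2.03 ± 0.04), Top2a (0.60 ± 0.04) and Tnnc2 (−1.52 ± 0.05). Averaged over both diets, 16269 genes differed between the times, 7883 higher and 8386 lower at 24 weeks, or 64.4% higher in place of 48.5% without the filter on dim probes. Among genes well above background on all arrays 7878 were higher and 6839 lower. The adipocyte, secretory, myofibroblast, stress, hypoxia, macrophage, endothelial and skeletal muscle calls held with an estimated correlation, with examples Plin1 (−6.48 ± 0.06), Ptgs2 (2.49 ± 0.06), Hif1a (0.84 ± 0.04), Cldn5 (1.87 ± 0.06) and Chrna1 (−2.14 ± 0.04). The averaged macrophage call is not an effect common to both diets. Macrophage genes were higher on chow (median 1.91) but leaned lower on the high-fat diet, with a median interaction of −2.40. Across genes, which are not independent replicates, the diet effects at 12 and 24 weeks correlated at r = 0.27 (Spearman rho 0.26). At both times 1324 genes were higher, against 525 if the calls were independent, and 1909 were lower, against 1051. Another 478 were higher at 12 weeks and lower at 24, against 822, and 643 were lower and then higher, against 671. The time effects on chow and on the high-fat diet correlated at r = 0.50 (rho 0.41), with 3650 genes higher on both diets, against 1534, and 3301 lower, against 1657. In opposite directions, 1251 were higher on chow and lower on the high-fat diet, against 1853. The reverse held for 449, against 1372.

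**Figure D1:**
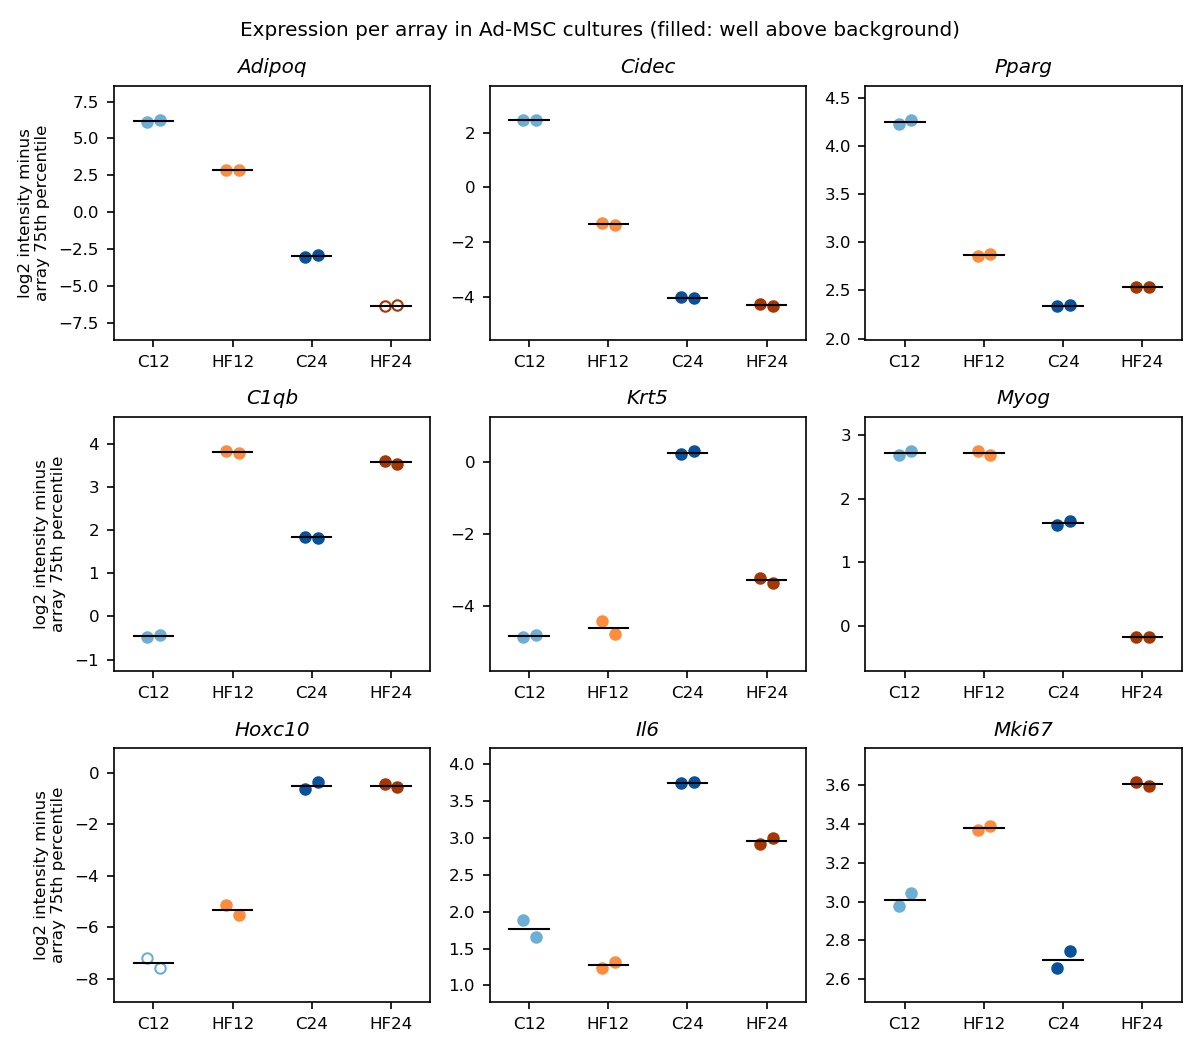
Each point is 1 array of C12, HF12, C24 or HF24, filled where the gene is well above background, and each line is a group mean. The vertical axis gives the log2 intensity minus the array's 75th percentile for 9 genes.

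**Figure D2:**
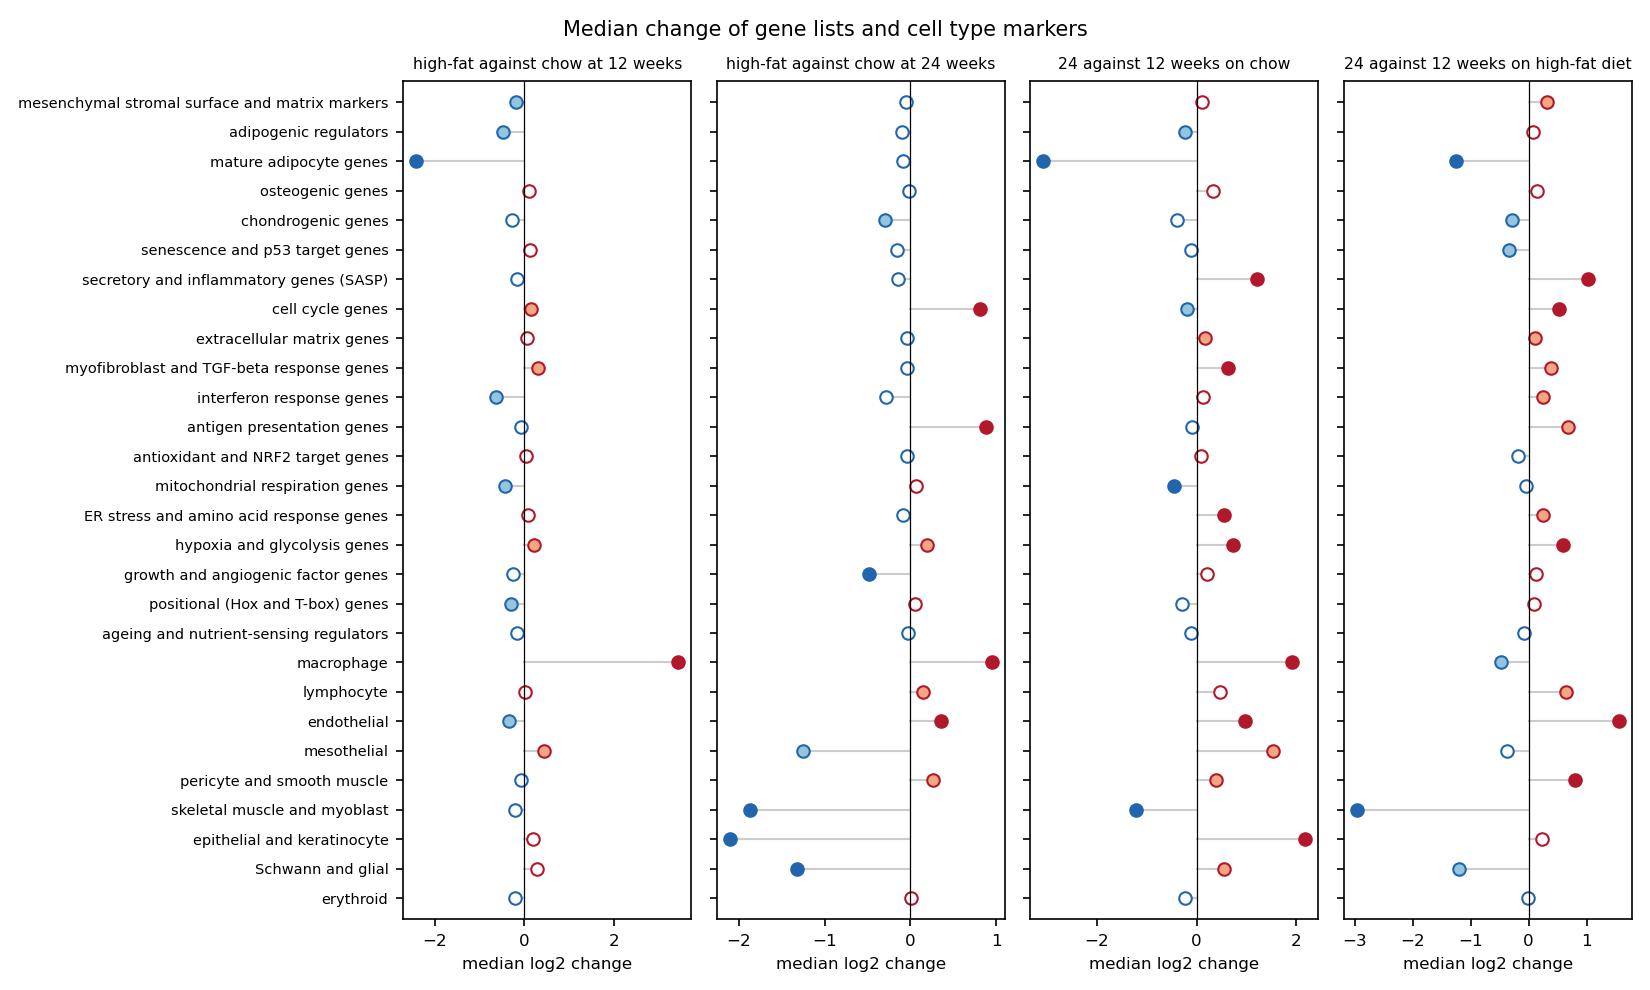
Median log2 change of 28 gene lists in 4 comparisons, red for higher and blue for lower. Dark points are lists called also with an estimated correlation between genes, light points those called only with the preset correlation, and open points those not called.

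**Figure D3:**
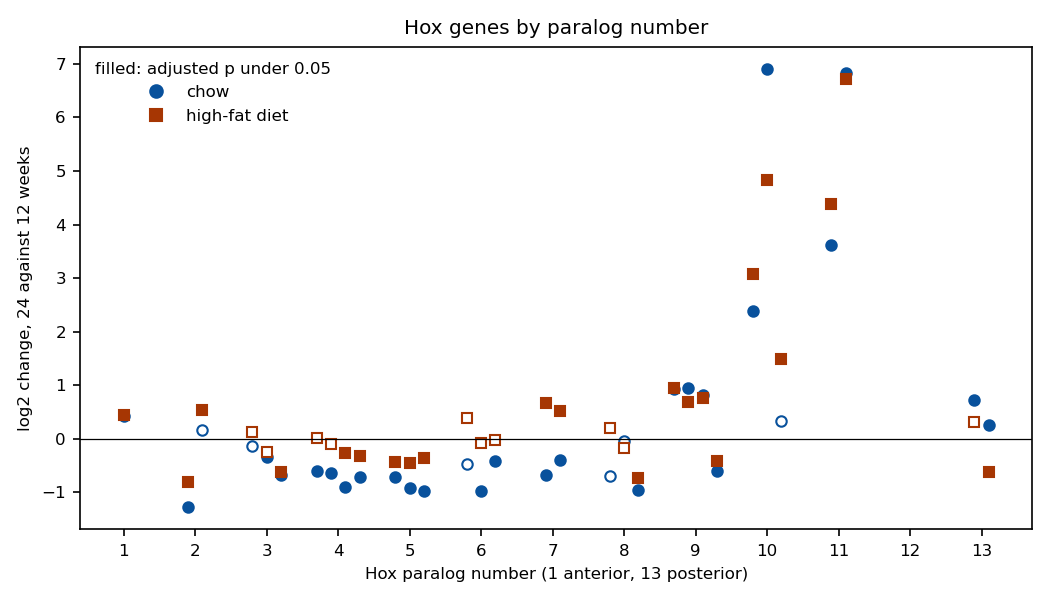
Log2 change of each measured Hox gene at 24 against 12 weeks, placed by paralog number from 1 (anterior) to 13 (posterior), with circles for chow and squares for the high-fat diet. Filled points have an adjusted p under 0.05.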

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

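Of the tests in this part, the spike-in probes, the scalings of the adipocyte list, the Hox position and diet tests, the count of groupings that keep each group whole, and the splits of the large calls by signal and by gene symbol were chosen only after the result was seen; the further adipocyte genes, the quantile normalization and the other groupings of the arrays were planned. A diet effect that differed between 12 and 24 weeks, by the interaction test, is what marks each result in the next 3 paragraphs: 8780 genes passed it. The lists that passed it had these median interactions: mesenchymal stromal (0.19), adipogenic regulator (0.23), mature adipocyte (1.82), cell cycle (0.68), interferon response (0.17), antigen presentation (0.53), mitochondrial respiration (0.47), positional (0.28), macrophage (−2.40), endothelial (0.65), mesothelial (−1.37), skeletal muscle and myoblast (−1.79), epithelial and keratinocyte (−2.18) and Schwann and glial (−1.76). With an estimated correlation these lists missed the threshold: mesenchymal stromal (adjusted p = 0.160), adipogenic regulator (adjusted p = 0.0829), interferon response (adjusted p = 0.209), antigen presentation (adjusted p = 0.136), mitochondrial respiration (adjusted p = 0.0576), positional (adjusted p = 0.210) and mesothelial (adjusted p = 0.123). Of 134 genes named in these comparisons, 114 were well above background on all 8 arrays, and 95 of those passed, 41 upward and 54 downward. Of the other 20, 15 passed, but their effects are partly bounds and are not listed. The list medians above keep any such genes at their own values.

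Adipocyte, adipogenic regulator, lipid and respiration genes had an interaction upward for Cidec (3.53), Agpat2 (2.20), Slc2a4 (2.61), Plin1 (1.68), Plin4 (1.97), Car3 (2.45), Pparg (1.58), Klf15 (1.56) and Acadm (0.85) and downward for Lpl (−0.48), Cd36 (−1.24), Dlk1 (−0.56) and Cpt1a (−0.66). These and the following values are log2 interactions. Macrophage and myeloid genes had an interaction downward for Mrc1 (−3.67), Fcgr1 (−2.58), C1qa (−2.41), C1qb (−2.54), C1qc (−1.98), Cd14 (−1.58), Cd68 (−2.36), Csf1r (−0.91), Itgam (−0.54), Aif1 (−2.04), Fcrls (−1.75), Ncf1 (−3.13), Acod1 (−1.49) and Spp1 (−2.12). Cytokine, interferon and antigen presentation genes had an interaction upward for Cxcl9 (4.99), Ubd (5.72), Gbp2 (1.77), Psmb9 (1.45), H2-Eb1 (0.63), Ifi44 (0.48) and Mmp3 (0.93) and downward for Tnf (−2.33), Ccl12 (−3.11), H2-Ab1 (−0.35), Isg15 (−0.32), Oas2 (−1.66), Oas3 (−1.77), Rsad2 (−1.60) and Icam1 (−0.70). Mast cell genes had an interaction upward for Mcpt4 (0.46), Cma1 (0.44) and Hdc (0.79). Cell cycle genes and their inhibitors had an interaction upward for Top2a (0.74), Nusap1 (0.83), Bub1 (0.66), Mki67 (0.53), Cenpf (1.17), Kif20a (1.18), Ccne1 (0.42), Mcm7 (0.79) and Rrm2 (0.68) and downward for Ccnd1 (−1.52), Cdkn1a (−0.53), Cdkn1c (−2.33), Cdkn2a (−1.15), Cdkn2b (−1.08) and Btg2 (−1.11). The call for Dlk1 was lost without any 1 array other than C12 replicate 1, C24 replicate 1 and HF24 replicate 1, with adjusted p from 0.0549 to 0.0728. The call for H2-Ab1 was lost without any 1 array other than C12 replicate 1, with adjusted p from 0.0586 to 0.129. The call for Ifi44 was lost without HF12 replicate 2 (adjusted p = 0.0519). The call for Isg15 was lost without any 1 array other than C24 replicate 2, with adjusted p from 0.0695 to 0.127. The call for Mcpt4 was lost without any 1 array other than C12 replicate 1, C24 replicate 2 and HF24 replicate 2, with adjusted p from 0.0526 to 0.0705. The call for Cma1 was lost without HF12 replicate 2 (adjusted p = 0.0518) or HF24 replicate 1 (adjusted p = 0.0546). The call for Cdkn1a was lost without any 1 array other than C12 replicate 2 and C24 replicate 1, with adjusted p from 0.0641 to 0.0894.

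Muscle genes had an interaction downward for Chrna1 (−1.79), Myog (−1.79), Tnnc2 (−1.83), Ttn (−1.90), Tcap (−1.25) and Myh1 (−1.45). Epithelial and Schwann cell genes had an interaction downward for Krt14 (−3.78), Krt5 (−3.78), Perp (−3.28) and Sox10 (−1.76). Vascular and pericyte genes had an interaction upward for Cldn5 (1.06), Cdh5 (0.83), Erg (0.85), Plvap (1.24), Tek (0.91), Vwf (0.39) and Kcnj8 (2.62) and downward for Des (−0.94) and Cnn1 (−0.50). Stromal and growth factor genes had an interaction upward for Nt5e (2.90), Dpp4 (1.32), Pgf (0.30) and Mdk (0.46) and downward for Alcam (−1.65), Tgfbi (−1.19), Ccn1 (−0.68), Id3 (−0.46), Igf2 (−1.99), Vegfd (−1.46) and Ptn (−1.88). Stress, hypoxia and positional genes had an interaction upward for Bnip3 (1.51) and Hoxa10 (0.69) and downward for Atf3 (−2.51), Chac1 (−0.76) and Car9 (−2.17). The call for Vwf was lost without any 1 array other than C12 replicate 1, with adjusted p from 0.0615 to 0.103. The call for Pgf was lost without any 1 array other than C24 replicate 1, with adjusted p from 0.0827 to 0.120.

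Adipocyte genes were lower at 24 than at 12 weeks, by a median of −3.08 on chow. Before any scaling between arrays, 6 spike-in probes shifted by a median of −0.161 (−0.211 to −0.147) from the 12-week to the 24-week slide row. Gene values had each array's 75th percentile subtracted, which already removes a shift common to a whole array. The spike-in shift therefore decides nothing about this pattern. Scaling between arrays is argued against, since the scaling that brought the list nearest to 0 left −2.90. Adipocyte cells in the 12-week cultures may account for the pattern on chow. On chow 32 of 35 further adipocyte genes outside the lists (91.4%) fell and 1 rose, against 22.0% of all genes that fell. On the high-fat diet only 20 of them fell and 3 rose, against 25.5% of all genes that fell. Lower expression of the same genes within the cells would lower them too, so the counts do not choose between these explanations. In C12 the abundant genes Adipoq and Car3 stood 6.19 and 6.76 above the 75th percentile on the log2 scale. Fat tissue expresses all 35, adherence and passaging would remove floating adipocytes, and these arrays do not separate carried-over adipocytes from adipocytes formed in culture. Age and feeding time stay open as untested biological explanations.

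Posterior Hox genes were higher at 24 than at 12 weeks: over both diets, 11 measured genes of paralogs 9 to 13 had 9 higher and 2 lower with a median of 0.92, or 0.83 with undetected members at their bound, against 2 higher and 11 lower of 21 for paralogs 1 to 8 with a median of −0.29. The unscaled spike-in shift of −0.161 argues against an overall intensity shift between slide rows. Between the diets at 12 weeks, where adipocyte genes were also lower, the 6 posterior genes well above background on all 12-week arrays had a median of 0.128 with quartiles of −0.16 and 0.16, 0 higher and 1 lower. Of the other 5, which have no level on some of these arrays, 1 was higher, Hoxc10 (at least 1.82-fold higher), and 3, named after their values were seen, were lower, Hoxd10 (at least 3.13-fold lower), Hoxa11 (at least 1.80-fold lower) and Hoxb13 (at least 1.57-fold lower), so loss of adipocytes stays open. The call for Hoxa11 was lost without HF12 replicate 2 (adjusted p = 0.0649). The call for Hoxb13 was lost without C12 replicate 1 (adjusted p = 0.0765) or HF12 replicate 1 (adjusted p = 0.0956). A sampling site further back along the body may account for it: the posterior minus anterior difference was 1.21, or 1.12 with undetected members at their bound (two-sided permutation p = 9e-05 for 1.21 over genes, which are not independent, with 100000 resamples), a test on the data that raised the idea. Age and feeding time stay open as untested.

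Large calls between the diets at 24 weeks leaned lower, with 402 higher and 1830 lower by at least 2-fold. Background at the dim end does not account for the lean. Among genes well above background on all arrays 82.3% were lower (229 higher and 1068 lower). Scaling changed the size of the lean but does not account for all of it. The share lower was 82.0% with the main scaling, 71.6% under quantile normalization and 74.6% with normexp before it. Normexp left only 159 and 467 such calls. Transcripts without a gene symbol had 88.8% lower, but the genes with a symbol leaned the same way, with 72.4% lower (255 higher and 669 lower), so they are not the whole pattern. No test separated the diet itself from a different mix of cells or from slide column, and all stay open.

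For the averaged diet effect, the 8 arrays were also split into all 35 groupings of 4 and 4 and fitted with 2 groups: 2 groupings gave as many genes, the real one with 458 and the split by feeding time and slide row with 6777. The split by time points to a structure of the samples; within a time the diet comparison called 9263 genes at 12 weeks and 9805 at 24. For the averaged time effect, 1 of 35 groupings gave as many, the real one with 6777, and the highest other gave 458. All groupings that part the 2 arrays of a group gave 0, which repeats of 1 sample would give as well, and only 3 keep each group whole, with 6777, 458 and 3 genes. These are too few for a share under 0.05, so the share among all 35 decides nothing for either effect. The time effect also follows slide row, and the diet effect follows slide column.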

How the results depend on the processing

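All alternatives here were planned, except that the median intensity took the place of the missing mean signal in normexp, chosen only after the files were seen. A block for slide or scan was not run, since there is 1 of each. All 7 counts of called genes stayed within 1.5 times their value under normexp with quantile normalization, quantile normalization, the value table of the authors, no filter, the strict filter, every kept probe, the variance trend and the replicate block, and so did the 4 counts that the 2 groups alone can give. Higher and lower calls at least 2-fold were fewer with normexp: 761 and 529 for diet at 12 weeks, 159 and 467 for diet at 24 weeks, 693 and 900 for time on chow, 413 and 744 for time on the high-fat diet and 584 and 891 for the interaction. Without 1 array, the count ran from 5440 to 8810 for diet at 12 weeks, 6717 to 9630 for diet at 24 weeks, 11111 to 13114 for time on chow, 9448 to 13735 for time on the high-fat diet, 6170 to 7670 for the interaction, 9548 to 11548 for diet averaged and 13843 to 15042 for time averaged. A lone array left in a group is assumed to vary like the other groups. Only diet at 12 weeks fell beyond 1.5 times in all, at 6077 without C12 replicate 1, 5440 without HF12 replicate 1 and 5825 without HF12 replicate 2; fewer arrays alone lower such a count, and no other cause was tested. Of the directions apart, the higher calls also fell beyond 1.5 times for diet at 24 weeks, to 2347 without C24 replicate 1, 2248 without HF24 replicate 1 and 2472 without HF24 replicate 2. They did so for time on the high-fat diet, to 3790 without HF12 replicate 1 and 4072 without HF24 replicate 1, and for the interaction, to 2446 upward without HF12 replicate 1.

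Of 105 list results called with all arrays, those that kept their call numbered 46 with an estimated correlation, 92 with normexp, 94 with quantile normalization, 105 with the value table, 95 without a filter, 99 with the strict filter, 102 with the variance trend and 105 with the replicate block. Leaving out 1 array kept 805 of 840, the 2 groups alone kept 53 of 59, and no list was called in the opposite direction in any of these. The median of 1 called list turned sign, that of extracellular matrix genes for time on the high-fat diet, at −0.01 under quantile normalization with or without normexp, where it was not called. Of 303 named gene results, 296 stayed on their side of the threshold with normexp, 297 with quantile normalization, 300 with the value table, 291 without a filter, 302 with the variance trend and 297 with the replicate block. With the strict filter 270 of 271 did, and with the 2 groups alone 192 of 197. Leaving out 1 array kept 2325 of 2424, and none of the named genes changed direction in a call. Without the filter on dim probes, the share of calls that were higher at 24 weeks was 67.7% in place of 52.8% on chow, 63.4% in place of 45.3% on the high-fat diet, and 64.4% in place of 48.5% averaged.

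The deviations of replicate numbers correlated between groups at r = −0.08 to 0.17 across genes, so the numbers do not pair the arrays. With replicate number as a block, diet at 12 weeks had 8041 called genes and diet at 24 weeks 8718. Signal over background limits the dim end: the lowest processed intensity well above background was 17.7 to 19.4 on the 12-week arrays and 26.5 to 33.8 on the 24-week arrays, so a dim gene has only a bound at 24 weeks sooner than at 12.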

Other observations

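The gene groups and genes in this part were all chosen after their values were seen, and no group test was run on them. Mast cell genes were higher at 24 weeks on both diets. Of 14 measured, 13 were higher and 0 lower (median 2.18) on chow. On the high-fat diet 13 were higher and 1 lower (median 2.72). The 1 lower was Mcpt8, which was well above background on only 1 of the HF24 arrays. Examples on chow are the protease genes Mcpt4 (2.76 ± 0.07), Cma1 (2.68 ± 0.06) and Cpa3 (2.85 ± 0.10) and the histamine synthesis gene Hdc (2.77 ± 0.11); on the high-fat diet they are Mcpt4 (3.22 ± 0.07), Cma1 (3.12 ± 0.06), Cpa3 (2.98 ± 0.10) and Hdc (3.56 ± 0.11). Between the diets the same 14 genes had 2 higher and 7 lower (median −0.26) at 12 weeks and 3 higher and 1 lower (median 0.17) at 24 weeks, so they went both ways.

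Of 13 cytotoxic lymphocyte genes measured, 7 were higher and 0 lower (median 0.83) at 24 weeks on chow and 11 were higher and 0 lower (median 1.61) on the high-fat diet, with the granzyme gene Gzmb (at least 5.02-fold higher) on chow and the interleukin receptor gene Il2rb (1.89 ± 0.16) on the high-fat diet. At 24 weeks the high-fat diet had 8 higher and 0 lower (median 0.51) among them, with Gzmb (1.14 ± 0.09). The lymphocyte list chosen beforehand did not pass for time on chow (median 0.47, adjusted p = 0.135), and its calls for time on the high-fat diet and for diet at 24 weeks missed with an estimated correlation (adjusted p = 0.0795 and adjusted p = 0.137).

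Sarcomere genes, which encode the contractile units of muscle fibres, were lower at 24 weeks on both diets. They are counted here with other muscle genes such as Ryr1, Casq1 and Pygm. Of 31 measured, 0 were higher and 31 lower (median −1.44) on chow. On the high-fat diet 0 were higher and 31 lower (median −3.28, or −3.21 with undetected members at their bound). Examples on chow are Ttn (−1.22 ± 0.08), Tcap (−2.92 ± 0.08) and Myh1 (−1.89 ± 0.05). At 24 weeks they were also lower on the high-fat diet than on chow, with 0 higher and 30 lower (median −2.11, or −1.98 with undetected members at their bound), for example Ttn (−2.22 ± 0.08), Tcap (−2.10 ± 0.08) and Myh1 (−2.46 ± 0.05). Of 11 major urinary protein genes, 0 were higher and 11 lower (median −5.27, or −5.25 with undetected members at their bound) for diet at 12 weeks and 0 were higher and 11 lower (median −9.82, or −8.33 with undetected members at their bound) for time on chow. Of 10 thermogenic adipocyte genes measured, 1 was higher and 7 lower (median −0.89) for diet at 12 weeks and 0 were higher and 7 lower (median −0.63) for time on chow.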
